A study of Homo sapiens with 28 samples.

How the data were processed

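Human 293FT cells, an established embryonic kidney line, were transfected with plasmids for EIF4ENIF1 (also called 4E-T, a protein that binds the cap-binding factor EIF4E and carries it to the nucleus and to P-bodies). In experiment 1 the plasmids carried Flag-tagged wild-type protein (WT), Q842P, a truncation that keeps residues 1-684, or no insert (vector). In experiment 2 they carried WT, R208H or GFP. Per the labels, each lysate was split: 20% gave a transcriptome library, and 80% was passed over affinity beads for translating ribosomes and gave a translatome library. There were 28 libraries in 14 groups with 2 replicates each. The 2 experiments had no control in common, so they were fitted apart, except where the WT effect of one was set against that of the other.

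The deposited values are raw counts per gene. Per the labels, the authors used Trim Galore 0.6.4, HISAT2 2.1.0, featureCounts 1.6.5 and the hg19 build. Neither the gene annotation, nor the strand setting, nor the handling of reads that map to several places is stated, so no coordinates are given. The tables hold 64985 features, and 8353 of them share a symbol with another feature. The values were checked to be whole numbers, and every column was matched to its sample. Total counts ran from 17430762 to 98923503 per library, so the spread between libraries limits precision more than counting error for most genes named. Counting error is large for features near 0 in a group, such as the GPANK1 feature with WT (0.411 and 0.115 CPM), and for the RF00017 features. Read duplicates could not be told apart, since no molecular identifiers are described.

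Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, the filterByExpr filter on low counts, quasi-likelihood fits with robust spread, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. One fit per layer and experiment held all its genotypes, so that groups of 2 libraries shared the estimate of spread (4 residual degrees of freedom in experiment 1, 3 in experiment 2). Fits tested 22335 genes in the translatome and 24752 in the transcriptome of experiment 1, and 26573 and 22648 in experiment 2. Translational efficiency was the difference of log2 fold changes between layers, tested as an interaction in a fit over both layers. Fold changes are log2 values with a standard error, taken as the size of the change divided by the square root of its F statistic. This error restates the test and is not a separate measure of spread. Levels are CPM, counts scaled by the library total, either per library with the SD or as TMM-normalised group means. The p-values rest on the spread between these replicate libraries only, and culture, capture and library preparation cannot be separated within a replicate.

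Genes were named by a rule fixed before the data were examined: past the threshold, with a mean log2 CPM of at least 3 and both libraries of one group above both of the other, the 8 largest changes each way in a translatome comparison (4 each way for the transcriptome and for efficiency, the latter without the separation condition), plus up to 4 members of each fixed list with the lowest adjusted p. EIF4ENIF1, EIF4E, DDX6, LSM14A and PATL1 were always read. Features with clone-based names and pseudogenes of listed genes were skipped. Fewer genes are named than the rule allows, with a preference, set after seeing the data, for those whose call held in all alternatives, and any gene outside the rule is said to have been chosen after its values were seen. Where named genes are said to hold in the alternatives, this is partly set by that preference. It does not show how stable the other calls are.

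The 25 gene lists were also fixed then: EIF4ENIF1 partners with P-body, decapping and deadenylation factors, translation initiation factors, cytosolic and mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits, mitochondrially encoded proteins, the integrated stress, unfolded protein, heat shock, interferon and immediate early responses, DNA replication, mitosis, replication-dependent histones, cholesterol synthesis, growth mRNAs described as EIF4E-sensitive, p53 targets, proteasome subunits, zinc finger genes named ZNF, snoRNA host genes, nuclear-retained noncoding RNAs, glycoproteins made at the endoplasmic reticulum, premature ovarian insufficiency genes, and markers of blood or endothelial cells and of fibroblasts or keratin-rich lines. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. No list call in a genotype comparison held with the estimated correlation (0 of 156 calls).

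Pairing was checked from the residuals of each layer: the libraries of one lysate correlated between layers at -0.16 to 0.22 in experiment 1 and -0.01 to 0.08 in experiment 2. As the labels describe a split lysate, efficiency was also fitted with the culture as a block. The labels do not tie equal replicate numbers of different genotypes to a common day, so a block on them is an alternative setting, but their residuals correlated at 0.28 to 0.42 in the translatome of experiment 2.

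The comparisons were tested on simulated data with 200 changed genes per comparison, drawn from the spread of the real libraries. Of genes simulated at 2-fold, 11.9% were called for 1-684 against vector and 10.4% for WT against vector in the translatome of experiment 1, against 94% for WT against GFP in experiment 2. At 4-fold these shares were 93.9%, 93.9% and 97%. False calls (genes left unchanged) were 7 of 78, 10 of 82 and 17 of 178 in these comparisons. They were 43 of 295 for R208H against GFP in the transcriptome and 19 of 112 for R208H against WT in efficiency. Their share exceeded the adjusted p threshold in most comparisons. In efficiency it stayed below for Q842P against vector (0 of 51), 1-684 against vector (2 of 45) and Q842P against WT (1 of 38). It also did for the translatome difference of the WT effect (1 of 48). A list raised 1.5-fold was called in 28 of 28 simulated comparisons with either correlation. The simulated genes varied independently of each other. This therefore does not show how often the test with an estimated correlation finds a list whose genes vary together.

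Alternatives planned before the data were examined were other size factors (RLE), the DESeq2 1.42.0 test, no filter on low counts, a replicate block, counts thinned to the smallest library, EIF4ENIF1 counts removed, only the groups compared in the fit, and each replicate left out in turn. Alternatives added after seeing the data left out one translatome library of 1-684, removed smooth trends on GC content and gene length from each library, and summed the features of a symbol for GPANK1, LY6G5B, HSD17B8 and CSNK2B. GC content and length came from a reference annotation of another build, matched by gene identifier (58597 features had a value).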

Results

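The series asks how extra EIF4ENIF1, and altered forms of it, change which RNAs human 293FT cells hold and which of those RNAs sit on translating ribosomes. Experiment 1 had 4 constructs (vector, WT, Q842P and the 1-684 truncation) and experiment 2 had 3 (GFP, WT and R208H), each with 2 transcriptome and 2 translatome libraries. Total counts per library ran from 23227973 to 29345015 for the transcriptome and from 25515527 to 67879434 for the translatome of experiment 1. In experiment 2 they ran from 24361598 to 98923503 and from 17430762 to 36240788. Mitochondrially encoded RNAs took 1.25% to 1.75% of the counts of every transcriptome library, but 6.79% to 20.2% in the translatomes of experiment 1 and 0.63% to 1.11% in those of experiment 2. The translatome library of 1-684 replicate 1 stood apart from the others of experiment 1: its mitochondrial share was 6.79%, against 14.8% for replicate 2, and the mitochondrial ribosomal RNA MT-RNR2 took 0.752% of its counts, against 4.96%.

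EIF4ENIF1 (ENSG00000184708.18) encodes 4E-T, a repressor of translation that binds the cap-binding protein EIF4E and the P-body helicase DDX6. In the transcriptome of experiment 1 its level was 10.9 ± 2.07 CPM (SD, n = 2) with vector, 424 ± 54.9 CPM with WT, 399 ± 165 CPM with Q842P and 31.4 ± 10.7 CPM with 1-684. In experiment 2 the transcriptome level was 102 ± 4.65 CPM with GFP, 20477 ± 655 CPM with WT and 19335 ± 33.6 CPM with R208H. The ratio of means to the control was thus 38.95 for WT, 36.72 for Q842P and 2.88 for 1-684 in experiment 1, and 200.56 for WT and 189.37 for R208H in experiment 2. The control levels differ as well (10.9 CPM with vector, 102 CPM with GFP), so the ratios of the experiments are not over a common baseline. The cause of the higher level with GFP was not tested. Translatome levels were 7.68 ± 2.84 CPM (vector), 114 ± 15.5 CPM (WT), 199 ± 141 CPM (Q842P) and 14.7 ± 0.948 CPM (1-684) in experiment 1, and 48.8 ± 4.86 CPM (GFP), 27280 ± 2734 CPM (WT) and 37782 ± 7022 CPM (R208H) in experiment 2. For 1-684 the increase over vector did not pass the threshold in either layer (log2 fold change 1.49 ± 0.35, adjusted p = 1, and 0.70 ± 0.47, adjusted p = 0.444).

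**Figure D1:**
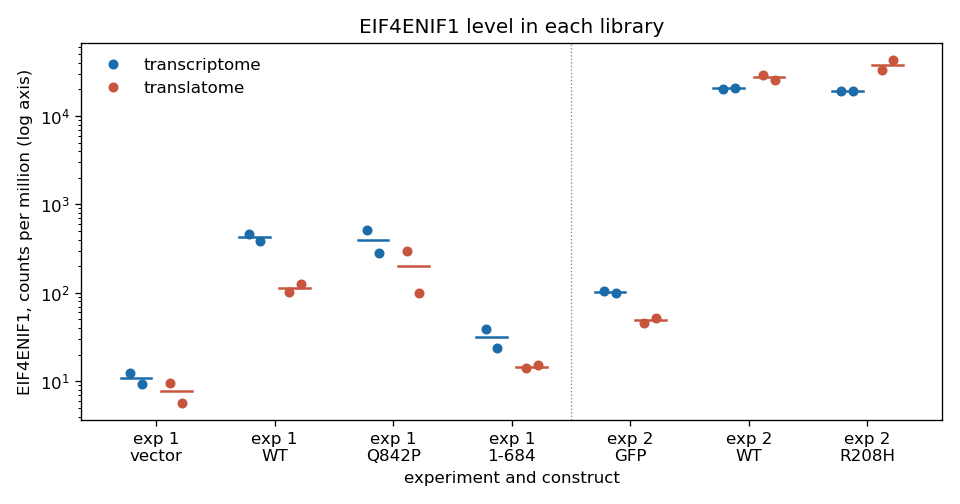
Level of EIF4ENIF1 in CPM (log axis) in each library of the 7 construct groups, for the transcriptome and the translatome; points are libraries and lines are group means of 2. Transcriptome means run from 10.9 CPM with vector to 20477 CPM with WT of experiment 2, and 1-684 has a mean of 31.4 CPM.

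The comparison of the layers in control cells asks which RNAs the ribosome capture enriches. With vector, all 13 mitochondrially encoded mRNAs were higher in the translatome, among them MT-CO1, a subunit of cytochrome c oxidase, at 33780 against 631.7 CPM (log2 difference 5.74 ± 0.45, adjusted p = 6.77e-10). The immediate early gene IER2 was higher by 5.59 ± 0.33, the ribosomal protein RPL8 by 4.04 ± 0.38 and the cell cycle factor E2F1 by 7.17 ± 0.50. Lower in the translatome were 28 of 48 replication-dependent histones, whose mRNAs mostly lack poly(A) tails, with 2 higher. Under GFP in experiment 2, IER2 was again higher (6.68 ± 0.22), but all 13 mitochondrially encoded mRNAs were lower, as MT-ATP6 shows (-4.16 ± 0.20), and so were 67 of 79 cytosolic ribosomal proteins, with 6 higher. In that layer comparison RPL27 was at -4.62 ± 0.24 and SDHD, a subunit of succinate dehydrogenase, at -5.92 ± 0.22. In all, 8191 genes were higher and 7749 lower with vector, and 11041 higher and 9285 lower with GFP. The balance with vector turned with RLE size factors (7937 higher and 8138 lower) and with thinned counts (7753 and 7793). Removing GC and length trends lowered the median size of these changes from 2.14 to 1.36 with vector and from 2.2 to 1.03 with GFP, and 12946 of 14800 and 14417 of 18672 genes kept their direction. The mitochondrial list had a median of 4.09 with vector (adjusted p = 2.57e-09, and adjusted p = 0.372 with an estimated correlation) and of -2.82 with GFP (adjusted p = 5.73e-07, and 0.957 with an estimated correlation). With those trends removed the list did not pass with GFP (median -0.67, adjusted p = 0.553), and MT-ND3 turned to 0.53. The difference between the experiments was not tested, and the libraries of the layers differ in GC content as well (44.2% to 46% of counted bases in transcriptomes, 48.9% to 51.7% in translatomes).

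WT against vector in experiment 1 asks what wild-type EIF4ENIF1 does to ribosome-bound RNA. Every one of the 79 cytosolic ribosomal proteins had a higher mean with WT (median log2 fold change 0.58), and so did 71 of 76 nuclear-encoded subunits of oxidative phosphorylation (median 0.58). Histone mRNAs were shifted the same way, with 32 of 35 above 0 and a median of 0.71. These list shifts passed at the preset correlation (adjusted p = 4.75e-28, 1.49e-19 and 6.27e-09) but not with an estimated correlation (adjusted p = 0.732, 0.732 and 0.424), and no member passed when adjusted over the list alone. EIF4E (0.07 ± 0.35), DDX6 (-0.51 ± 0.27), LSM14A (0.02 ± 0.28) and PATL1 (0.15 ± 0.41), the partners of 4E-T, did not pass. Genes past the threshold were 2 of 22335: EIF4ENIF1 itself (4.26 ± 0.53, adjusted p = 0.0376) and LY6G5B, a surface antigen of the MHC region (4.38 ± 0.41, adjusted p = 0.00158), a feature named after its values were seen. The EIF4ENIF1 call ended on leaving out any of the 4 libraries, and the count was then 1 (without WT replicate 1 or 2), 2 (without vector replicate 1) or 4 (without vector replicate 2). LY6G5B has 7 features under its symbol, and their sum changed by 0.86 ± 0.35 (adjusted p = 0.965).

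In the transcriptome of WT against vector, EIF4ENIF1 rose by 5.24 ± 0.40 (adjusted p = 0.00233). AL096701.3, which overlaps EIF4ENIF1 on the other strand in the reference annotation, rose by 4.74 ± 0.37. GPANK1, a G-patch protein of the MHC region, fell by 6.34 ± 0.36 (adjusted p = 4.8e-05) in one of its 7 features, while their sum changed by -0.17 ± 0.20 (adjusted p = 1). AL096701.3 and GPANK1 were named after their values were seen, and these were the only 3 calls among 24752 genes. Without vector replicate 2 the count was 2 and EIF4ENIF1 was not called, and AL096701.3 was not called without either vector replicate. Translational efficiency gave 0 calls in edgeR, 1 call in DESeq2 and 1 call with the culture as a block. At unadjusted p under 0.05 there were 1288 of 27839 genes, below the share of 0.05 that no change would give. Efficiency of the ribosomal proteins had a median of 0.64 (adjusted p = 4e-21, and 0.482 with an estimated correlation).

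Q842P against vector asks the same of EIF4ENIF1 with a substitution near the C-terminus. The ribosomal proteins and oxidative phosphorylation subunits leaned down rather than up, with medians of -0.14 and -0.29 (adjusted p = 0.0263 and 3.25e-06, and 0.972 for both with an estimated correlation). This lean rested on single libraries: the ribosomal protein median was 0.11 without vector replicate 2 and 0.08 without Q842P replicate 2, and the oxidative phosphorylation call ended without either (medians -0.01 and -0.14). The ribosomal protein call also ended with GC and length trends removed (adjusted p = 0.0649). EIF4ENIF1 rose by 4.62 ± 0.54 (adjusted p = 0.0119), while EIF4E (0.10 ± 0.35), DDX6 (0.11 ± 0.26), LSM14A (0.19 ± 0.28) and PATL1 (0.32 ± 0.39) did not pass. The other 3 calls were a clone-named feature, AC012314.23 (2.97 ± 0.37), and a pair of features named RF00017, copies of the signal recognition particle RNA family (-5.08 ± 0.45 and -4.72 ± 0.59), all named after their values were seen. Without vector replicate 2 the count was 73, without Q842P replicate 2 it was 7, and EIF4ENIF1 was not called without vector replicate 1 or vector replicate 2. One RF00017 feature was not called without either Q842P replicate, and with only these groups in the fit the count was 0, so none of the 4 was called. In the transcriptome 3 genes were called: EIF4ENIF1 (5.21 ± 0.40, adjusted p = 0.00245), AL096701.3 (4.72 ± 0.37) and the same single feature of GPANK1 (-6.15 ± 0.35). Without vector replicate 2 the count was 1 and EIF4ENIF1 was not called, and AL096701.3 was not called without either vector replicate. Efficiency gave 0 calls in edgeR and 0 calls in DESeq2. At unadjusted p under 0.05 there were 753 of 27839 genes, below the share of 0.05 that no change would give. Leaving out Q842P replicate 1, Q842P replicate 2 or vector replicate 1 gave 1 call each.

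The 1-684 truncation lacks the C-terminal part of the protein, and its comparison with vector asks what the remaining part does. In the translatome EIF3B, a scaffold subunit of the initiation factor eIF3, rose to 203.9 from 22.46 CPM (3.18 ± 0.39, adjusted p = 0.0196). The Src-family kinase FYN rose to 38.9 from 6.08 CPM (2.68 ± 0.34, adjusted p = 0.0203), and CCN2, a secreted target of YAP signalling, to 77.84 from 16.82 CPM (2.21 ± 0.30, adjusted p = 0.0216). ZFP36L2, which promotes decay of mRNAs with AU-rich elements, rose by 1.5 ± 0.27 (adjusted p = 0.0294), as did the ubiquitin ligase SIAH2 by 2.11 ± 0.36. RN7SL4P, a copy of the signal recognition particle RNA, fell by 2.65 ± 0.31 (adjusted p = 0.0196). EIF4E (-0.51 ± 0.35), DDX6 (-0.33 ± 0.26), LSM14A (0.17 ± 0.28) and PATL1 (-0.17 ± 0.40) did not pass. In all 473 of 22335 genes were called, 436 higher and 37 lower. This balance rests on the controls: it was 115 higher and 225 lower without vector replicate 2, and 561 higher and 283 lower without vector replicate 1. All 13 mitochondrially encoded mRNAs had lower means (median -1.05, adjusted p = 5.23e-06, and 0.878 with an estimated correlation; not called without vector replicate 2, median -0.58). On this list the 2 libraries of 1-684 differed by 1.56, more than the change itself, and the median was -0.65 without 1-684 replicate 1 and -1.78 without 1-684 replicate 2. Of 28 immediate early genes 1 was called, and 6 were when adjusted over the list alone (median 0.59, adjusted p = 0.00174, and 0.878 with an estimated correlation; not called without 1-684 replicate 2, median 0.42, or with GC and length trends removed, median 0.32 and adjusted p = 0.068). Without 1-684 replicate 1 the count was 270, and 62 of the 473 genes were called without each of the 4 libraries. The count was 10 with only these groups in the fit (EIF3B, FYN and RN7SL4P still called, CCN2, ZFP36L2 and SIAH2 not), 139 with GC and length trends removed and 1256 in DESeq2.

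For 1-684 the transcriptome gave 1 call, the clone-named feature AC012314.1 (-1.91 ± 0.19, adjusted p = 0.0198, named after its values were seen), and it was not called without vector replicate 1 or vector replicate 2, with a count of 0. Without 1-684 replicate 1 or 1-684 replicate 2 the count was 6 or 11. EIF3B (3.16 ± 0.45), FYN (2.73 ± 0.40), CCN2 (2.34 ± 0.35), each with adjusted p = 0.00747, and YTHDF1, a reader of N6-methyladenosine (2.38 ± 0.37, adjusted p = 0.0102), were among the 11 genes with raised translational efficiency, and 0 genes were lowered. With the culture as a block the count was 50. It was 0 without vector replicate 2, 7 without vector replicate 1, 133 without 1-684 replicate 1 and 222 without 1-684 replicate 2.

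Comparing the altered forms with WT asks what the changes in the protein take away. For 1-684 the loss of the C-terminal part cannot be told apart from the lower counted level of EIF4ENIF1. That level was 31.4 CPM with 1-684 against 424 CPM with WT in the transcriptome, and 14.7 against 114 CPM in the translatome. With 1-684, EIF3B was higher than with WT (3.90 ± 0.41, adjusted p = 0.00147), and its efficiency was raised by 4.13 ± 0.46 (adjusted p = 0.000198). Copies of the signal recognition particle RNA were lower, RN7SL4P at -3.79 ± 0.33 (adjusted p = 0.000631) and RN7SL3 at -3.38 ± 0.35 (adjusted p = 0.00147). Respiratory and ribosomal genes were lower as well: the cytochrome c oxidase subunit COX7B at -1.86 ± 0.33, MT-ATP6 at -1.84 ± 0.40 and RPS29 at -1.66 ± 0.33, with LSM5, of the ring that binds deadenylated mRNA, at -2.17 ± 0.36. Of 79 ribosomal proteins 20 were called, all lower, and 51 when adjusted over the list alone (median -0.93, adjusted p = 1.34e-23, and 0.507 with an estimated correlation). Of 76 oxidative phosphorylation subunits 23 were called, all lower, and 40 when adjusted over the list alone (median -0.81, adjusted p = 4.88e-21, and 0.402 with an estimated correlation). EIF4ENIF1 itself was lower with 1-684, at -3.56 ± 0.51 (adjusted p = 0.006). In all 1152 genes were higher and 703 lower. The 1855 calls became 5 without WT replicate 1 and 7 without WT replicate 2, all of them lower, and 714 without 1-684 replicate 2 (606 higher and 108 lower). Of the genes just named, RN7SL4P and RN7SL3 were still called without either WT library in the translatome, and the others there were not, nor was RPS29 without 1-684 replicate 2 or MT-ATP6 with GC and length trends removed. For efficiency 277 genes were higher and 78 lower. The count was 655 with the culture as a block, 2 without WT replicate 1, 5 without WT replicate 2 and 697 without 1-684 replicate 2. The efficiency call of EIF3B held in each.

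Q842P against WT put all 79 ribosomal proteins lower in mean (median -0.74, adjusted p = 3.37e-31, and 0.626 with an estimated correlation) and 72 of 76 oxidative phosphorylation subunits (median -0.92, adjusted p = 1.91e-32, and 0.545 with an estimated correlation). Of the subunits 0 were called over all genes and 40, all lower, when adjusted over the list alone. EIF4ENIF1 did not differ past the threshold (0.36 ± 0.46). The 6 calls over all genes were the 2 RF00017 features (-4.85 ± 0.45 and -4.37 ± 0.60), AC012314.23 (2.99), AL365357.1 (-3.83), AL591846.1 (-3.03) and one feature of LY6G5B (-2.74 ± 0.36), outside the naming rule and named after their values were seen. The sum over the LY6G5B features changed by -0.97 ± 0.35 (adjusted p = 0.434). That count was 2 without WT replicate 1, 1 without WT replicate 2 and 3 without Q842P replicate 1, and 647 with only these groups in the fit, and 0 of the 6 were among the 363 calls of DESeq2. One RF00017 feature was called without each library, and the other not without WT replicate 2 or either Q842P replicate. AL365357.1 and AL591846.1 were not called without any 1 of the 4 libraries, and LY6G5B and AC012314.23 not without either WT replicate, nor LY6G5B without Q842P replicate 1. In this translatome comparison DESeq2 gave no adjusted p to 50275 of its 52922 features. The absence of the 6 from its calls therefore does not count against them. In efficiency 1 gene was called, against 336 with only these groups in the fit, 99 with no filter and 10 in DESeq2. That gene was the transcription factor OVOL3 (-4.36 ± 0.67, adjusted p = 0.0387, named after its values were seen). It was not called without any 1 of the 4 library pairs, with RLE size factors, with thinned counts or with GC and length trends removed. With the culture as a block 49 genes were called, without WT replicate 2 the count was 0, and without WT replicate 1 or Q842P replicate 2 it was 2. At unadjusted p under 0.05 the transcriptome had 517 of 24752 genes, below the share of 0.05 that no change would give. Its count of calls was 0 in edgeR and 5 in DESeq2. It was 1 without WT replicate 2 or Q842P replicate 1 and 2 without Q842P replicate 2. For 1-684 against WT the transcriptome gave 5 calls, EIF4ENIF1 (-3.75 ± 0.37, adjusted p = 0.0153), AL096701.3 (-3.12), AC012314.1 (-2.50 ± 0.20) and single features of GPANK1 (6.49 ± 0.36) and HSD17B8 (-2.49 ± 0.30), the last 4 named after their values were seen. The sums over features were 0.13 ± 0.20 for GPANK1 and -1.08 ± 0.22 for HSD17B8 (adjusted p = 0.999 for both). That count was 2 without WT replicate 1 and 9 without either 1-684 replicate, and EIF4ENIF1 was not called without WT replicate 1 or 1-684 replicate 2, nor AL096701.3 and HSD17B8 without either WT replicate.

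WT against GFP in experiment 2 asks the question of WT again, at a higher level of the transgene. RPS25, a protein of the small ribosomal subunit, rose to 377.4 from 123.3 CPM (1.61 ± 0.17, adjusted p = 0.000445), and RPL41 by 1.03 ± 0.17 (adjusted p = 0.00603). Some mitochondrially encoded mRNAs rose with them (6 of 13, with 1 lower), MT-CO3 to 454.2 from 167.4 CPM (1.44 ± 0.21, adjusted p = 0.00388) and MT-ND4L by 1.33 ± 0.17 (adjusted p = 0.00132), as did NDUFB4 and ATP5MC3 of complex I and the ATP synthase (0.94 ± 0.17 and 0.94 ± 0.15). The Hsp70 relative HSPA1L rose by 1.62 ± 0.26 and DDIT4, an inhibitor of mTORC1, by 1.01 ± 0.17. Genes of cell division fell: DLGAP5, of the mitotic spindle, to 46.21 from 95.02 CPM (-1.04 ± 0.16, adjusted p = 0.00457), and the kinesins KIF20B (-0.81 ± 0.14) and KIF14 (-0.84 ± 0.15). The zinc finger gene ZNF791 (-1.26 ± 0.19), the nucleotide kinase AK9 (-1.48 ± 0.18) and the calcium channel subunit CACNB2 (-1.35 ± 0.19) fell as well. Of the P-body factors, PAN3 of the deadenylase (-0.83 ± 0.17), DCP1A (-0.67 ± 0.15) and DCP2 (-0.69 ± 0.17) of the decapping complex fell, while EIF4E (0.05 ± 0.15), DDX6 (-0.32 ± 0.16), LSM14A (-0.03 ± 0.15) and PATL1 (0.10 ± 0.24) did not pass. In all 1131 genes were higher and 1094 lower, of 26573. The 2225 calls became 745 without WT replicate 2, 357 without GFP replicate 1 and 117 without GFP replicate 2. RPL41, NDUFB4, ATP5MC3, PAN3, DCP1A and DCP2 were not called without GFP replicate 1 or GFP replicate 2 (the last 3 also not without WT replicate 2). DDIT4 was not called without GFP replicate 1, nor KIF20B and KIF14 without GFP replicate 2. PAN3, DCP1A and DCP2 were also not called with GC and length trends removed.

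Among the gene lists of this comparison, 49 of 79 cytosolic ribosomal proteins were called, all higher (73 when adjusted over the list alone; median 0.65, adjusted p = 8.21e-37, and 0.229 with an estimated correlation). Of 76 oxidative phosphorylation subunits 24 were called, all higher (42 over the list alone; median 0.45, adjusted p = 1.85e-15, and 0.219 with an estimated correlation). Of 13 mitochondrially encoded genes 6 were higher and 1 lower (median 0.67, adjusted p = 7.58e-05, and 0.296 with an estimated correlation). Mitochondrial ribosomal proteins had 9 higher of 78 (median 0.24, adjusted p = 2.55e-06, and 0.413 with an estimated correlation). Mitosis genes had 12 lower of 53 (19 lower and 2 higher over the list alone; median -0.22, adjusted p = 7.58e-05, and 0.415 with an estimated correlation). Zinc finger genes had 55 lower and 6 higher of 503 (median -0.24, adjusted p = 2.55e-06, and 0.413 with an estimated correlation), with a median of -0.09 once GC and length trends were removed. Smaller shifts passed for heat shock genes (3 higher, median 0.21, adjusted p = 0.00795, and 0.666 with an estimated correlation), EIF4E-sensitive growth mRNAs (3 higher and 1 lower, median 0.21, adjusted p = 0.035, and 0.415 with an estimated correlation) and snoRNA host genes (2 higher, median 0.20, adjusted p = 0.0262, and 0.52 with an estimated correlation). None of these 3 passed without WT replicate 2 (adjusted p = 0.32, 0.175 and 0.233), nor the growth mRNAs without GFP replicate 2 (adjusted p = 0.0581) or the snoRNA host genes with GC and length trends removed (adjusted p = 0.0543). The other lists did not pass: P-body and partner genes had 1 gene higher and 6 lower, initiation factors 1 higher, the integrated stress response 3 higher, the unfolded protein response 2 higher and 1 lower, the interferon response 2 higher and 3 lower, and immediate early genes 2 higher and 1 lower. DNA replication genes had 1 higher, histones 2 higher and 3 lower, cholesterol synthesis 1 lower, p53 targets 2 higher and 2 lower, the proteasome 1 higher and 1 lower, nuclear-retained noncoding RNAs 2 lower, glycoproteins 2 higher and 2 lower, and premature ovarian insufficiency genes 2 lower. Markers of blood or endothelial cells and of fibroblasts or keratin-rich lines had 0 calls (8 and 10 genes tested in edgeR).

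**Figure D2:**
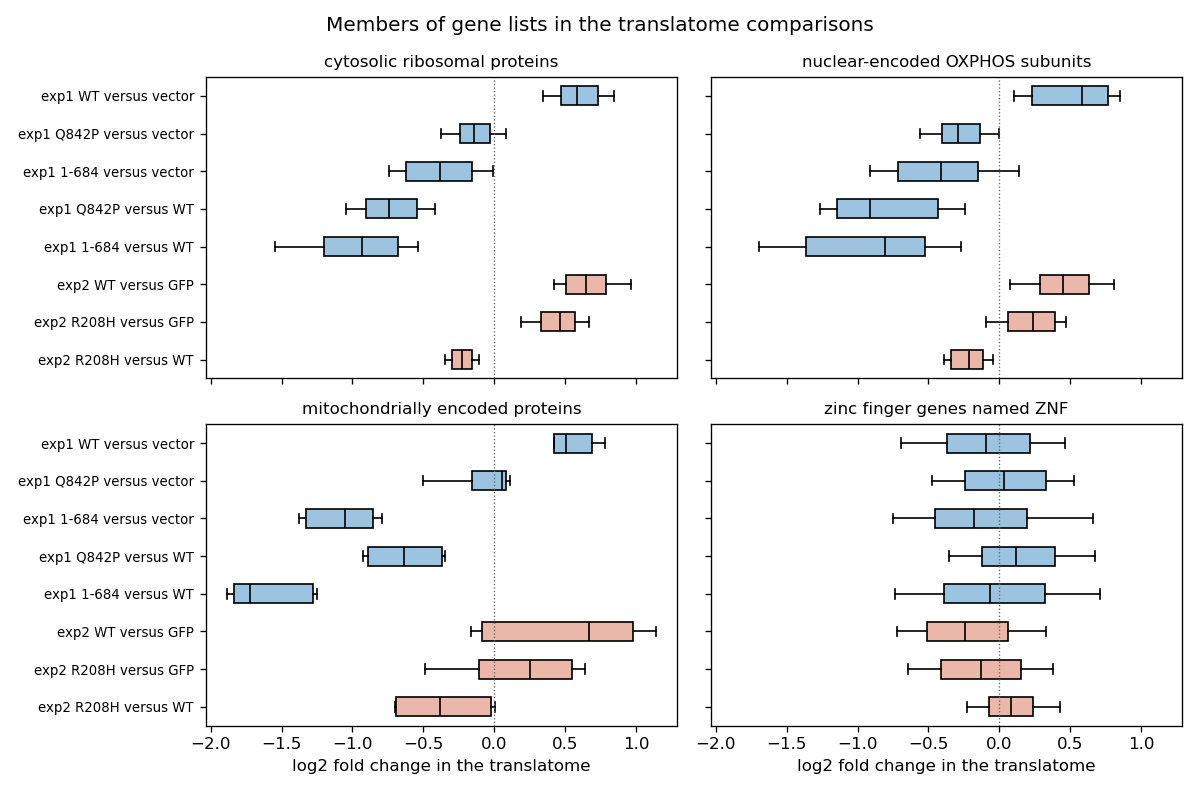
Log2 fold changes in the translatome of the members of 4 gene lists (cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits, mitochondrially encoded proteins and ZNF genes) in 8 comparisons; boxes span the quartiles with the median, and whiskers the 10th to 90th percentiles. The ribosomal protein median is 0.58 for WT against vector, 0.65 for WT against GFP and 0.47 for R208H against GFP. It lies below 0 for Q842P and 1-684 against vector. For Q842P it turns to 0.11 without vector replicate 2 and 0.08 without Q842P replicate 2. For 1-684 it is -0.12 without vector replicate 2 and -0.18 without 1-684 replicate 2.

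In the transcriptome WT lowered SNHG15, a snoRNA host gene (113.7 against 230.8 CPM, -1.02 ± 0.10, adjusted p = 9.51e-05), and the histone HIST1H2AC (-0.96 ± 0.12, adjusted p = 0.000791). LEAP2, an antagonist of the ghrelin receptor, fell by 1.87 ± 0.14 (adjusted p = 1.62e-06). RUNDC1 (-2.12 ± 0.22, adjusted p = 0.00286) and LYG1, related to lysozyme (-1.77 ± 0.20), fell too. ANKRD1, a target of YAP signalling, rose by 0.72 ± 0.10 (adjusted p = 0.00198). SFI1, which overlaps EIF4ENIF1 on the other strand in the reference annotation, rose by 4.43 ± 0.10, and EIF4E (0.25 ± 0.09) and DDX6 (0.32 ± 0.12) did not pass. In all 128 genes were higher and 322 lower, of 22648, a balance that turned in DESeq2 (482 higher and 391 lower). Histones had 9 lower of 46 (11 over the list alone; median -0.31, adjusted p = 6.47e-06, and 0.214 with an estimated correlation). Of the snoRNA host genes 6 of 20 were lower (11 over the list alone; median -0.29, adjusted p = 1.48e-05, and 0.391 with an estimated correlation). The count was 194 without WT replicate 1, 258 without GFP replicate 1 and 720 without GFP replicate 2, and the genes named here were called in each.

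Translational efficiency with WT rose for RUNDC1 (1.81 ± 0.31, adjusted p = 0.0069), MT-ND4L (1.40 ± 0.26, adjusted p = 0.0069), MT-CO3 (1.38 ± 0.28, adjusted p = 0.0147) and RPS25 (1.27 ± 0.24, adjusted p = 0.00986), and fell for KIF20B (-0.99 ± 0.23, adjusted p = 0.0311). Of the ribosomal proteins 1 was called and 4 when adjusted over the list alone (median 0.46, adjusted p = 2.51e-18, and 0.801 with an estimated correlation). In all 140 genes were higher and 156 lower. RLE size factors moved the median over all genes by 0.138, with 444 of 593 calls higher, and KIF20B was not called with them. The count was 62 without GFP replicate 2, 105 without GFP replicate 1, 548 without WT replicate 2 and 740 without WT replicate 1. Of these 54, 88, 397 and 158 were higher and 8, 17, 151 and 582 lower, so the balance rests on single libraries. It also turned in DESeq2 (827 higher and 333 lower), with no filter (227 and 163), with the culture as a block (192 and 154), with thinned counts (302 and 237), with only these groups in the fit (141 and 107) and with GC and length trends removed (97 and 45). MT-ND4L was not called without GFP replicate 1, MT-CO3 and RPS25 not without either GFP replicate, and KIF20B not without those or WT replicate 1.

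R208H against GFP asks what raised EIF4ENIF1 with this substitution does, and does not tell the raised level from the substitution. The substitution itself is read from R208H against WT, given further below. In the translatome DHRS2, a short-chain dehydrogenase, rose to 14.16 from 5.17 CPM (1.45 ± 0.17, adjusted p = 0.00292), as it did with WT (1.45 ± 0.17, adjusted p = 0.00117), and RPS25 rose by 1.29 ± 0.16 (adjusted p = 0.00309). CLPTM1L, a membrane protein, fell to 12.17 from 34.22 CPM (-1.47 ± 0.21, adjusted p = 0.0077). So did ATMIN, a cofactor of the ATM kinase (-1.34 ± 0.20), and KIF20B (-0.78 ± 0.14, adjusted p = 0.0191). Mitosis genes had 7 lower of 53 (22 lower and 1 higher over the list alone; median -0.34, adjusted p = 9.9e-11, and 0.442 with an estimated correlation). Ribosomal proteins had 2 higher of 79 (46 over the list alone; median 0.47, adjusted p = 6.57e-20, and 0.442 with an estimated correlation). In all 277 genes were higher and 329 lower. The count was 16 without GFP replicate 2, 69 without GFP replicate 1, 279 without R208H replicate 1 and 298 without R208H replicate 2. The last 2 turned the balance (173 higher and 106 lower, and 188 higher and 110 lower), as did no filter (879 of 1721 higher) and the replicate number as a block (1257 higher and 1202 lower). RPS25 and ATMIN were not called without GFP replicate 2, and KIF20B not without it, GFP replicate 1 or R208H replicate 1, nor with GC and length trends removed.

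In the transcriptome R208H raised DDX6, the helicase partner of 4E-T, to 28.66 from 16.46 CPM (0.80 ± 0.11, adjusted p = 0.00175), the chaperone HSP90AB1 by 0.59 ± 0.09 (adjusted p = 0.00175) and SAMD9, an antiviral factor, by 1.16 ± 0.16 (adjusted p = 0.00119). LEAP2 (-1.94 ± 0.14, adjusted p = 9.06e-07) and SNHG15 (-0.91 ± 0.10, adjusted p = 0.000302) fell, as with WT. Of 21 heat shock genes 5 were higher (9 over the list alone; median 0.28, adjusted p = 8.24e-06, and 0.35 with an estimated correlation). In all 238 genes were higher and 386 lower. The count was 155 without R208H replicate 1, 244 without GFP replicate 1 and 254 without R208H replicate 2 (153 higher and 101 lower), and the genes named here were called in each. Efficiency was higher for 5 genes and lower for 25, among them ATMIN (-1.78 ± 0.26, adjusted p = 0.00177; not called without R208H replicate 1) and KIF20B (-1.36 ± 0.23, adjusted p = 0.0121; not called without R208H replicate 1 or GFP replicate 1). The efficiency count was 422 in DESeq2, 470 with only these groups in the fit, 105 with no filter and 96 with thinned counts. That count was 14 without R208H replicate 1. The balance turned to 36 higher and 5 lower without GFP replicate 1, and to 29 higher and 18 lower without GFP replicate 2, with 5 and 11 calls shared.

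R208H and WT did not part past the threshold in any layer of experiment 2. DDX6 was 0.48 ± 0.11 higher with R208H in the transcriptome (adjusted p = 0.226), so its rise over GFP is not shown to differ between the constructs. EIF4ENIF1 differed by 0.40 ± 0.22 in the translatome (adjusted p = 0.518). Ribosomal proteins had a median of -0.23 in the translatome (adjusted p = 3e-10, and 0.324 with an estimated correlation), and mitochondrially encoded genes one of -0.39 (adjusted p = 8.95e-06, and 0.231 with an estimated correlation), with 6 of 13 lower when adjusted over the list alone. The 3 counts of 0 in edgeR stood beside 26, 44 and 35 calls in DESeq2 (translatome, transcriptome and efficiency). At unadjusted p under 0.05 edgeR had 2882 of 26573, 1542 of 22648 and 1755 of 28421 genes. Each lies above the share of 0.05 that no change would give, so the counts of 0 do not show the constructs to be alike. Leaving out 1 replicate gave 220 translatome calls without WT replicate 1, 5 without R208H replicate 1 and 18 without R208H replicate 2. It gave 53 efficiency calls without WT replicate 1, 12 without WT replicate 2, 9 without R208H replicate 1 and 33 without R208H replicate 2. In the transcriptome it gave 50 without WT replicate 1, 19 without WT replicate 2, 46 without R208H replicate 1 and 64 without R208H replicate 2. In the translatomes of experiment 2, libraries with equal replicate numbers correlated in their residuals (0.418, 0.285 and 0.318), and with the replicate number as a block 20 translatome and 2 transcriptome genes differed between R208H and WT. With that block the translatome counts against GFP were 4404 for WT and 2459 for R208H.

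Effects of different constructs share their control libraries, so their correlation across genes was set against 20 simulations with the same sharing and no effect. Genes are not independent replicates. In the translatome the effects of WT and R208H correlated at 0.675 in experiment 2, against 0.501 simulated. They shared 180 higher and 239 lower genes (11.8 and 13.5 expected from the numbers called, leaving the shared control aside), RPS25 and DHRS2 among the higher and KIF20B among the lower, with 0 genes called in opposite directions. In experiment 1 the correlation was 0.379 for WT and Q842P (0.519 simulated), 0.196 for WT and 1-684 (0.507 simulated) and 0.527 for Q842P and 1-684 (0.523 simulated). The simulations leave out any link between libraries of equal replicate number. Where these correlate as their residuals do, with equal spread, the value with no effect would be 0.584 for WT and R208H. The excess there may thus be smaller than the simulations give. The gene sets are unlike, however: the residuals cover 9267 genes with a mean log2 CPM of at least 3, and the effects 26573 genes. For the pairs of experiment 1 the value with no effect would be 0.496, 0.352 and 0.6 (residuals of 7325 genes, effects of 22335). Leaving out a control library raises the simulated values as well. Without vector replicate 1 the correlations were 0.584, 0.488 and 0.704 (0.706, 0.694 and 0.71 simulated), and without vector replicate 2 they were 0.76, 0.621 and 0.781 (0.747, 0.736 and 0.749 simulated). WT and 1-684 thus stayed below the simulated value with each of the libraries left out, and the other 2 pairs lay on either side of it. The simulations give each gene the same spread in all groups. The real translatome replicates differed unequally, with a chi-square per degree of freedom of 287.2 for 1-684, 127.5 for vector, 71.47 for Q842P and 38.55 for WT. A shared control that varies more than both constructs, as for WT and Q842P, would raise the value with no effect, not lower it. Unequal spread is not in the simulations, so a value below the simulated one is still not shown to be an effect. WT and Q842P gave 0.453 without Q842P replicate 2 (0.429 simulated), and Q842P and 1-684 gave 0.367 without 1-684 replicate 2 (0.411 simulated). WT and R208H gave 0.731 and 0.755 without GFP replicate 1 or 2 (0.687 and 0.697 simulated), a smaller excess than with all libraries.

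The WT effect was tested for a difference between the experiments, which share no library. EIF4ENIF1 in the translatome rose less in experiment 1 (4.26) than in experiment 2 (9.33), a difference of -5.07 ± 0.62 (adjusted p = 0.00406). RUNDC1 and LEAP2 in the transcriptome changed by 0.06 and 0.15 in experiment 1 and by -2.12 and -1.87 in experiment 2, differences of 2.17 ± 0.31 (adjusted p = 0.0217) and 2.01 ± 0.30 (adjusted p = 0.0309). In all 3 translatome and 6 transcriptome genes differed, and ribosomal proteins did not as a list in the translatome. Across genes the effects correlated at 0.246 (Spearman 0.3) in the translatome, and at -0.014 (Spearman -0.039) in the transcriptome. Over the genes with a mean log2 CPM of at least 3 in both experiments they were 0.456 (Spearman 0.482, 6372 genes) and 0.047 (Spearman -0.093, 7323 genes). Translatome replicates within experiment 1 groups also differed along WT minus GFP of experiment 2. Over 8518 genes, replicate 2 minus replicate 1 correlated with it at -0.358 (Q842P), 0.258 (WT), -0.173 (1-684) and 0.108 (vector). The translatome correlation is therefore not shown to be an effect of WT. Without WT replicate 2 of experiment 1 the translatome count was 0 and EIF4ENIF1 was not called. The count was 1 without replicate 2 of WT or GFP of experiment 2 and 8 without vector replicate 2. In the transcriptome SFI1 was the 1 remaining call without WT replicate 1, WT replicate 2 or vector replicate 1 of experiment 1, so RUNDC1 and LEAP2 were not called then. The count was 3 without vector replicate 2, 17 without WT replicate 2, 50 without GFP replicate 1 and 25 without GFP replicate 2 of experiment 2. RUNDC1 and LEAP2 were also not called without WT replicate 1 of experiment 2, nor RUNDC1 without vector replicate 2 of experiment 1 or LEAP2 without WT replicate 2 of experiment 2.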

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

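The test for a capture nearer to that of experiment 2, the test on summed features of GPANK1 and its neighbours, and the count of genes called without each library were chosen after the result was seen, and the removal of GC and length trends was an alternative added after seeing the data.

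In 9 results the effect of WT differed between the experiments by a test of the difference itself, with experiment 2 subtracted from experiment 1. EIF4ENIF1 in the translatome differed by -5.07 ± 0.62 (adjusted p = 0.00406), which goes with its higher level in experiment 2. AL096701.3 in the translatome (-5.27 ± 0.71, adjusted p = 0.0192) and SFI1 in the translatome (-2.98 ± 0.45, adjusted p = 0.0192) and transcriptome (-3.64 ± 0.22, adjusted p = 3.09e-07) overlap EIF4ENIF1 on the other strand, and their reads were not separated from those of the transgene. In the transcriptome RUNDC1 differed by 2.17 ± 0.31 (adjusted p = 0.0217), LEAP2 by 2.01 ± 0.30 (adjusted p = 0.0309), the zinc finger gene ZSCAN16 by 1.19 ± 0.17 (adjusted p = 0.0203), AC025171.1 by 1.51 ± 0.23 (adjusted p = 0.0313) and the pseudogene RP9P by 1.33 ± 0.21 (adjusted p = 0.0438). Each of these 5 fell in experiment 2 (ZSCAN16 by 0.92) and did not pass in experiment 1 (ZSCAN16 at 0.28). The experiments differ in control plasmid (GFP or empty vector) and in transgene level, and these were not tested apart. Their transcriptome libraries differ as well. GAPDH ran from 765 to 1636 CPM in experiment 1 and from 111 to 149 CPM in experiment 2. The GC content of counted bases was 45.3% to 46% and 44.2% to 44.6%. Differences in culture or library preparation therefore cannot be told apart from control plasmid or transgene level. RUNDC1 and ZSCAN16 were not called without any 1 library of experiment 1 or without WT replicate 1 of experiment 2. RP9P in the transcriptome and AL096701.3 in the translatome were not called without any 1 of the 8 libraries. LEAP2 and AC025171.1 were not called without WT replicate 1, WT replicate 2 or vector replicate 1 of experiment 1 or WT replicate 1 of experiment 2, nor LEAP2 without WT replicate 2 of experiment 2. In the translatome SFI1 was not called without a WT replicate of experiment 1 or a WT or GFP replicate of experiment 2, nor EIF4ENIF1 without WT replicate 2 of experiment 1.

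In the translatome of 1-684, 473 genes were called against vector, among them EIF3B and FYN. A single deviating library is argued against for 62 of them, EIF3B and FYN included, which were called without each of the 4 libraries in turn. For the others it cannot be told apart from an effect of the construct. Of the 473 calls 351 were shared without vector replicate 1, 109 without vector replicate 2, 175 without 1-684 replicate 1 and 216 without 1-684 replicate 2, and without vector replicate 2 the calls were 115 higher and 225 lower. The changes of the pairs with equal replicate numbers correlated across genes at 0.402, above the bound written beforehand, but the crossed pairs gave 0.17, and the numbers are not shown to pair these libraries, so that bound decides nothing. Removal of GC and length trends left 139 calls, under the bound written beforehand for a GC or length bias, but 449 of 451 called genes with a GC value kept their direction and 121 were called in both; their median fold went from 1.56 to 1.27 (standard error 0.31 and 0.30), so such a bias may account for a part, a reading made more cautious after these values were seen. A capture or library preparation nearer to that of experiment 2 cannot be told apart from an effect of the construct, since the change correlated across genes at 0.243 with the difference between experiments (0.165 for replicate 1, 0.263 for replicate 2, and 0.318 for Q842P), between the bounds set. An effect of the truncated protein stays open and untested. The EIF4ENIF1 level with 1-684, endogenous gene included, was 31.4 CPM in the transcriptome against 10.9 CPM with vector, and gene counts do not settle whether the construct was poorly expressed or is poorly counted.

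Ribosomal protein genes such as RPS25 were higher with WT than with GFP in the translatome of experiment 2, with a list median of 0.65. Removal of GC and length trends left a median of 0.571, which argues against these as the whole source, and the list median differed by at most 0.152 between the 2 libraries of a group of experiment 2, which argues against spread within those groups. In experiment 1, however, the same list differed between replicates by 0.281 to 0.463. An axis along which translatome libraries vary within groups cannot be told apart from an effect of WT: a replicate difference of experiment 1 correlated across 8518 genes with WT minus GFP at up to 0.358 in size, against 0.469 for WT minus vector, and genes are not independent replicates. A gain of ribosomal protein mRNAs on ribosomes under WT thus remains a hypothesis, and the list did not pass with an estimated correlation (adjusted p = 0.229).

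GPANK1 fell by 6.34 ± 0.36 in one feature in the transcriptome of WT against vector, but the sum of its 7 features changed by -0.17 ± 0.20 (adjusted p = 1). That feature held 20.9 and 21.4 CPM with vector, out of 179 and 164 CPM for all 7 features. Its loss alone would move the sum little. The sum therefore cannot tell reads moving between features of the same symbol from a loss of that feature. No biological explanation was tested. The sums of LY6G5B (0.86 ± 0.35 for WT against vector in the translatome) and HSD17B8 (-1.08 ± 0.22 for 1-684 against WT in the transcriptome) were not called either. Both changed by more than the GPANK1 sum, so they are not shown to be unchanged. The sum of LY6G5B was lower with 1-684 than with WT in the translatome (-1.70 ± 0.36, adjusted p = 0.0181).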

How the results depend on the processing

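The settings that removed GC and length trends, left out the translatome library of 1-684 replicate 1 alone, or summed features of a symbol were chosen after seeing the data, and the others were planned. Fits without 1 replicate leave a group with a single library, which is assumed to vary like the other groups, and all of them keep the fit's pooled spread. With groups of 2 libraries the spread between replicate libraries, not depth, limits these results, and thinning to the smallest library moved few counts. The cause of the changes below was not tested, except that no filter adds genes with low counts and leaving out groups or libraries lowers the degrees of freedom. TL, TX and TE stand for translatome, transcriptome and efficiency, and each value is a count of called genes unless said otherwise.

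Without one replicate the counts ran in TL from 1 to 4 (WT against vector), 5 to 73 (Q842P against vector), 270 to 844 (1-684 against vector), 1 to 5 (Q842P against WT), 5 to 1480 (1-684 against WT), 117 to 2933 (WT against GFP), 16 to 298 (R208H against GFP) and 0 to 220 (R208H against WT). In TX, in the same order, they ran from 2 to 4, 1 to 4, 0 to 11, 0 to 2, 2 to 9, 194 to 720, 155 to 867 and 19 to 64. In TE they ran from 0 to 1, 0 to 1, 0 to 222, 0 to 2, 2 to 697, 62 to 740, 14 to 47 and 9 to 53. The layer counts ran from 11373 to 12876 (vector) and 16626 to 16917 (GFP), and differences of the WT effect from 0 to 8 in TL and 1 to 50 in TX. Correlations of effects ran from 0.283 to 0.76 (WT and Q842P), 0.173 to 0.621 (WT and 1-684), 0.367 to 0.781 (Q842P and 1-684) and 0.504 to 0.755 (WT and R208H), and those of the WT effects of both experiments from 0.116 to 0.234 in TL and -0.057 to 0.006 in TX. Genes called in every one of these fits numbered 62 for 1-684 against vector in TL (EIF3B, FYN and RN7SL4P among them), 4 for 1-684 against WT, 83 for WT against GFP (RPS25 and MT-CO3 among them) and 11 for R208H against GFP.

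With no filter, counts in experiment 1 were 35, 68, 1285 (against vector) and 239 (Q842P against WT) in TL, 19, 16, 46, 16 and 17 in TX, and 21 (WT), 338 (1-684), 99 (Q842P against WT) and 980 (1-684 against WT) in TE. In experiment 2 they were 1721 (R208H) and 119 (R208H against WT) in TL, 1298, 1416 and 236 in TX, and 105 (R208H) and 44 (R208H against WT) in TE. The differences of the WT effect numbered 27 in TL and 89 in TX, and correlations were 0.466 (WT and 1-684), 0.504 (WT and R208H) and 0.036 (WT effects in TL). With DESeq2 the counts were 13, 13, 1256, 363 (Q842P against WT) and 2827 (1-684 against WT) in TL, 6 (WT), 6 (1-684) and 5 (Q842P against WT) in TX, and 1 (WT), 271 (1-684), 10 and 1240 (against WT) in TE of experiment 1. In experiment 2 DESeq2 gave 1020 (R208H) and 26 (R208H against WT) in TL, 873 (WT) and 44 (R208H against WT) in TX, 1160, 422 and 35 in TE, and 41 differences of the WT effect in TX. With only the groups compared in the fit, they were 4, 0, 10 and 647 (Q842P against WT) in TL, 12 (WT), 0 (1-684) and 4 (Q842P against WT) in TX, and 1 (WT), 2 (1-684), 336 and 122 (against WT) in TE of experiment 1, then 1364 (R208H, TL), 15 (R208H against WT, TX), 470 and 1 (R208H and R208H against WT, TE) and 37 (WT effect, TX).

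With GC and length trends removed, counts were 0 (WT), 139 (1-684) and 1033 (1-684 against WT) in TL, 0 (1-684) and 2 (1-684 against WT) in TX, and 35 (1-684), 0 (Q842P against WT) and 186 (1-684 against WT) in TE of experiment 1. In experiment 2 they were 1444 (WT) and 237 (R208H) in TL, 816, 1141 and 43 in TX, 142 (WT) in TE, and 12 differences of the WT effect in TX. Under this setting single-gene differences between layers that changed sign included COL1A1 (-1.24 with vector, -1.43 with GFP), JUN (-0.16 with GFP) and MT-ND3 (0.53 with GFP). The zinc finger median for WT against GFP in TL was -0.09 with it. With the culture as a block TE counts were 1 (WT), 50 (1-684), 49 (Q842P against WT) and 655 (1-684 against WT). The labels tie equal replicate numbers to no common day; residuals of equal numbers correlated at -0.58 to 0.25 in TL and -0.24 to 0.69 in TX of experiment 1, and 0.28 to 0.42 and -0.20 to 0.19 in experiment 2. A block on the number gave 5 (WT), 2 (1-684), 2 (Q842P against WT) and 8 (1-684 against WT) in TX of experiment 1, 4404, 2459 and 20 in TL and 261, 338 and 2 in TX of experiment 2, and 6 and 17 differences of the WT effect.

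Without the TL library of 1-684 replicate 1, counts were 1 (WT against vector, TL), 179 (1-684, TE) and 713 (1-684 against WT, TE). Thinning gave 0 (Q842P against WT, TE), 6 (R208H against WT, TX), 539 (WT against GFP, TE) and 96 (R208H, TE). RLE factors gave 0 (Q842P against WT, TE) and 593 (WT against GFP, TE), and removal of EIF4ENIF1 gave 1 (WT against vector, TL). List calls numbered 156, 153 with RLE, 198 with no filter, 153 thinned, 157 without EIF4ENIF1 and 0 with an estimated correlation.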

Other observations

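The tests here come from the planned fits, and the genes were picked from those the naming rule gave after their values were seen.

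A few regulators were called in both layers of experiment 2. With WT the growth regulator MYC was higher in the translatome (0.62 ± 0.16, adjusted p = 0.0284) and the transcriptome (0.62 ± 0.13, adjusted p = 0.0222), while its noncoding neighbour PVT1 was lower (-1.0 ± 0.15, adjusted p = 0.00388, and -0.98 ± 0.20, adjusted p = 0.0201). The interferon-induced modifier ISG15 was lower in both (-0.82 ± 0.16, adjusted p = 0.0103, and -0.85 ± 0.14, adjusted p = 0.00482). With R208H, PVT1 was again lower in both (-0.66 ± 0.15, adjusted p = 0.038, and -1.10 ± 0.20, adjusted p = 0.00897). Their efficiency was not called with WT (MYC -0.11 ± 0.24, PVT1 -0.14 ± 0.27 and ISG15 -0.09 ± 0.26, adjusted p = 0.875, 0.866 and 0.916), nor that of PVT1 with R208H (0.36 ± 0.27, adjusted p = 0.622), which does not exclude a change of ribosome loading. None of the layer calls held without each single library: those of MYC and of PVT1 with WT in the transcriptome ended without WT replicate 1, WT replicate 2 or GFP replicate 1. Those of ISG15 with WT ended without GFP replicate 1 in both layers, without GFP replicate 2 in the translatome and without WT replicate 1 in the transcriptome. That of PVT1 with WT in the translatome ended without GFP replicate 2. MYC in the translatome was not called without WT replicate 2 or either GFP replicate. With R208H, PVT1 was not called in the translatome without any 1 of the 4 libraries, nor in the transcriptome without GFP replicate 1 or R208H replicate 1.

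The translatome libraries of the experiments differed in how the counts were spread over genes. Genes above 1 CPM numbered 13575 to 16048 in the translatome libraries of experiment 1 and 19830 to 20769 in those of experiment 2, against 16401 to 17678 and 14959 to 15780 in the transcriptome libraries. Of the counts in the translatomes, the 10 most abundant genes took 20.2% to 25.2% in experiment 1 and 5.33% to 10.2% in experiment 2.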
